A study of Mus musculus with 333 samples.

How the data were processed

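Single cells of wild-type mouse brain were enriched by FACS, captured on a Fluidigm C1 microfluidic device, reverse transcribed and amplified with the SMARTer kit from polyA RNA, and made into Nextera XT libraries, per the labels' protocols. The sort gate and the marker behind it are not given in the sources used here. The authors deposited raw counts, whole numbers of reads per gene for each of 333 cells in 1 table, with STAR and HTSeq version 0.6.0 as the tools and mm10 as the genome build, per the submitters' processing notes. The library method carries no molecular identifiers, so the values count reads and not molecules.

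The table held 22074 genes named by symbols in capitals. Of these, 21250 were matched to mouse gene symbols and 824 kept the symbol as given, 4850 had no read in any cell, and none was mitochondrial. Of 507 list entries, 11 (10 genes, among them Tubb3, Lhfpl3 and Rpl13) found no matching symbol and were not analysed here. Every column of the table matched 1 cell by its cell ID. Totals per cell ran from 374574 to 4849603 reads with a median of 1308901, and the lowest number of genes detected in a cell was 1011.

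Cells were grouped by the region and age in their titles and by the submitters' cell type label. Where title and source field differ, for the 51 E18.5 cells titled mThal, the title was used and the pooled value of both E18.5 sets was computed as an alternative. Cells labelled unannotated (53) or purple (7), a label without a stated meaning, entered no comparison. The libraries of 2 adult cells labelled Microglia had a Pearson correlation of 0.994 across genes (log2 CPM), against 0.638 for the next closest pair in the series, and were merged, which left 332 cells. Genes are not independent replicates, and this correlation is only a measure of closeness. No other doublet filter was used. The 24 cells of 272 that carried the markers of another class at 25% or more of that class's median stayed in and were left out in an alternative.

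With no label that ties cells to an animal, each set and cell type is 1 sample, so no p-value, standard error or count of changed genes was computed. For each cell type against all other named cells, and for 11 comparisons between ages, regions or types with at least 5 cells per arm, counts were summed over the cells of an arm and divided by their total (CPM). Log2 ratios had 1 CPM added to each arm, and a gene counted as measured at 10 CPM or more in either arm. Each of 43 gene lists, fixed before the data were examined together with the comparisons and the naming rule, was summarised by the number of measured members at least 2-fold higher or lower and by its median log2 ratio. A list median's percentile came from 10000 random lists of the same size matched on mean expression in 20 bins, and describes these libraries only.

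Shares of cells with a read were taken after thinning each cell to 700000 reads, which left out 33 cells and kept 299. Of the 10 adult astrocytes 3 reached that depth, so the shares behind the genes named for adult astrocytes rest on 3 cells. Sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals, both at 95%. A gene without a read in 1 arm has a fold against a floor of 3 reads over that arm, and a gene with 1 to 3 reads in 1 arm has the plain ratio with its counting interval.

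Genes were named by a rule of size. It took the 10 genes per direction (5 per cell type) with the largest log2 ratio among those with at least 50 CPM in the higher arm, a read in at least 50% of its cells, a share of cells 30 points above the other arm and a log2 ratio of at least 1 whichever cell was left out. Ribosomal protein genes, predicted genes and numbered transcripts were kept out of that ranking, and any member of a fixed list could be named. The rule gives more candidates than the text names. Results on single genes that the rule or a list would allow are in part not reported here.

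The steps were tested on simulated counts (gamma-Poisson) with the real totals per cell, the level and the spread between cells of each gene in the second arm, and changes of 2-, 4- or 8-fold put into 200 genes per comparison. Among unchanged genes, 43.0% (cell numbers of the endothelial comparison) to 67.9% (cell numbers of the comparison of myelinating oligodendrocytes by age and region) lay beyond 2-fold by chance, so a 2-fold difference of a single gene is within the noise between cells. Genes made 8-fold different had the right direction in 84.8% (E18.5 neurons) to 100% (adult endothelial cells). Lists of 10 genes raised 4-fold lay as low as percentile 6.10 with the cell numbers of the adult astrocytes, 34.1 with those of the myelinating oligodendrocytes by age and region, 60.2 with those of the P12 microglia by region and 72.8 with those of the E18.5 neurons, so a list can miss a real change in these comparisons. In the other comparisons the lowest was 98.6. The naming rule passed 101 unchanged genes against 945 genes observed for myelinating oligodendrocytes against OPCs, 256 against 751 for adult astrocytes, 142 against 222 for adult microglia, 75 against 320 for adult endothelial cells, 105 against 243 for thalamic astrocytes against those of visual cortex and 222 against 394 for E18.5 neurons. The simulated numbers came from 4804 to 8000 measured genes and the observed from 6851 to 8995. Both simulated arms had the spread of the second arm, so they lacked the differences in genes detected per cell between the real arms. The medians were 1294 against 3245.5 genes for myelinating oligodendrocytes against OPCs and 1666 against 3266 for adult astrocytes. The simulated numbers may therefore be too low there, and the contrast cannot by itself show an excess over noise. Of 200 unchanged lists of 10 genes per comparison, 3% (astrocytes of hippocampus against visual cortex) to 7.50% (microglia of the same regions) fell in the outer 5% of random lists.

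Settings chosen beforehand for repeating the computations included the mean of single-cell CPM, TMM factors (edgeR) and median-of-ratios factors between the summed arms, 0.1 and 5 CPM added, no minimum and a minimum of 50 CPM, leaving out cells with the markers of another class or with under 1000 genes, each cell left out in turn, and, for single comparisons, the blocks of cell IDs, adult visual cortex alone, the pooled E18.5 sets and smaller draws of cells. Others were chosen after seeing the data and are named as such where they appear. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. Positions of single genes came from the GENCODE vM21 annotation of GRCm38.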

Results

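Single cells of wild-type mouse brain were profiled at embryonic day 18.5 (E18.5), at postnatal day 12 (P12) and in adults, with polyA RNA of each cell sequenced as a library of its own. By title the 333 libraries form 6 sets, with 71 libraries from visual cortex and 51 titled mThal at E18.5, 60 from visual cortex, 68 from hippocampus and 21 from thalamus at P12, and 62 from adult visual cortex. The source field of the 51 libraries titled mThal reads visual cortex, so they are called E18.5 titled mThal here. Libraries held between 374574 and 4849603 reads counted to genes, with a median of 1308901. The median per set ran from 1092859 reads and 1958 genes detected per cell in adult visual cortex to 1605202 reads in E18.5 titled mThal and 3365 genes in E18.5 visual cortex.

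The design text gives 5 mice per stage, and no label ties a cell to an animal. Each cell type in each set is therefore 1 sample, no comparison has replicates and none has a test. The adult set, both E18.5 sets and P12 thalamus each held a separate run of cell IDs. What such a run stands for is not given, and in comparisons with these sets age and region cannot be told apart from it. Levels are in CPM, the reads of a gene summed over the cells of an arm and scaled by the total reads of that arm, and log2 ratios were taken with 1 CPM added to each arm. Ranges come from leaving out each cell in turn, and a cell that alone moved a list median by over 1.5 times is given by its number in the titles with the median without it. Counting intervals (exact Poisson, 95%) and the intervals of shares cover counting error only. Members of a list are called higher or lower from a difference of 2-fold. A list median "at the floor" has its genes without a read in 1 arm set to 3 reads over that arm, the value behind each fold given as "at least". Such a fold allows for counting error only and not for the spread between cells, so it is no lower limit where few cells carried the reads. The median log2 ratio over all measured genes lay between -0.19 and 0.02 in the comparisons of astrocytes by region and of P12 thalamus with E18.5, and it stands beside the lists in the others. Numbers of cells with a read are given after thinning to 700000 reads, without shallower cells. Percentiles place a list median among random lists matched on expression. A value that TMM or median-of-ratios scaling is said to add is the log2 shift of its factors. With 1 CPM added, the log2 ratios of genes near 0 in an arm moved by less than that.

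The E18.5 visual cortex set was made almost wholly of neurons, with 65 of 71 cells (91.5%, Clopper-Pearson interval 82.5 to 96.8%). In E18.5 titled mThal, 5 of 51 cells were labelled Neurons (9.80%, 3.26 to 21.4%), 17 were astrocytes and 25 were unannotated. Astrocytes made up 21 of 60 cells in P12 visual cortex, 19 of 68 in P12 hippocampus and 16 of 21 in P12 thalamus (76.2%, 52.8 to 91.8%). Myelinating oligodendrocytes were found in P12 hippocampus (15 cells) and adult visual cortex (6 cells), and the adult set was led by 23 endothelial cells of 62 (37.1%). All 15 of P12 hippocampus lay in a separate block of lower cell numbers with 1 astrocyte, and the other hippocampal cells held none. No P12 or adult cell carried the label Neurons, which at 0 of 62 adult cells allows a share of up to 5.78% (Clopper-Pearson), or 4.84% as 3 counts of the total. Cells were enriched by FACS with a gate the labels do not describe, so these shares are those of the sort. With both E18.5 sets pooled, as the source field reads, neurons were 57.4% of 122 cells.

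**Figure D1:**
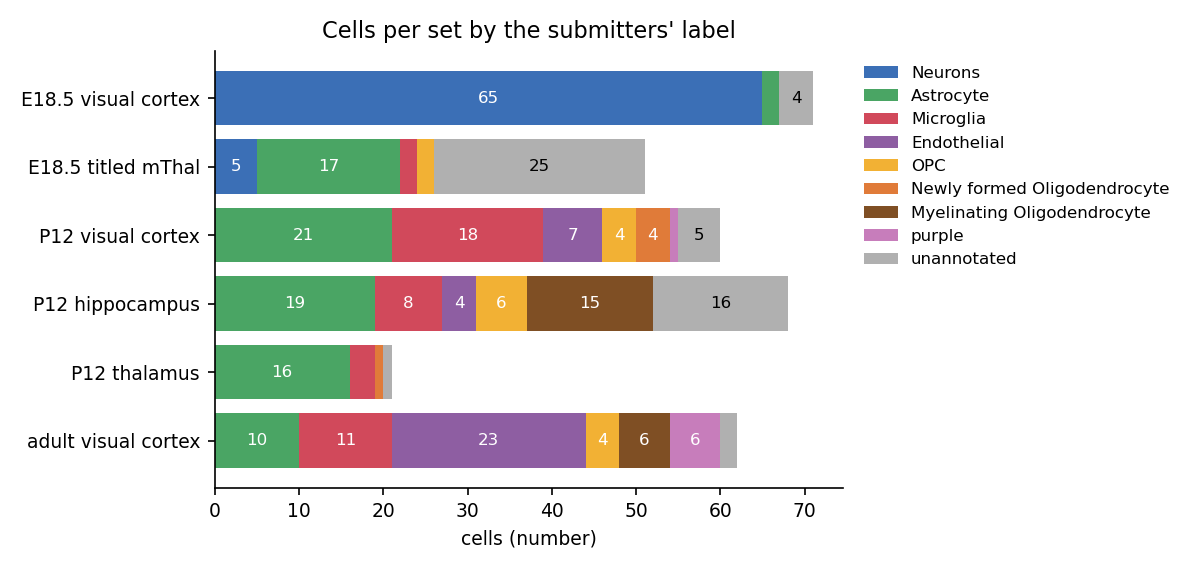
Number of deposited libraries (x axis) in each of the 6 sets (y axis), stacked by the submitters' cell type label. Neurons fill 65 of 71 libraries in E18.5 visual cortex, unannotated cells 25 of 51 in E18.5 titled mThal, and endothelial cells 23 of 62 in the adult set, whose 11 microglia libraries count as 10 cells after a near-identical pair is merged.

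Each named cell type carried the markers of its label, which follows from the labels if the submitters set them from these counts. In neurons, 11 of 11 measured neuron markers were at least 2-fold above the other named cells (median log2 ratio 4.88, range 4.42 to 5.31). Stmn2, a tubulin-binding protein of growing axons, was at 1308 against 6.60 CPM. Astrocytes had all 12 astrocyte markers higher (median log2 ratio 6.56, range 6.45 to 6.67). The angiotensinogen gene Agt was at 785 against 0.0534 CPM and the water channel Aqp4 at 3004 against 13.4 CPM. All 12 microglia markers (median log2 ratio 7.77, range 7.73 to 8.46, 8.46 without P12 visual cortex cell 48) and all 12 endothelial markers (median log2 ratio 8.19, range 8.08 to 8.51) were higher in their own type, among them the complement receptor C3ar1 (2069 against 2.38 CPM) and the VEGF receptor Flt1 (log2 ratio 10.58). Oligodendrocyte precursor cells (OPCs) had 10 of 11 OPC markers higher (median log2 ratio 3.46, range 3.20 to 4.06, 4.06 without P12 hippocampus cell 15). Pdgfra, the receptor for platelet-derived growth factor, was at 4899.5 against 14.6 CPM. Newly formed oligodendrocytes, 5 cells, had 11 of 12 of their markers higher (median log2 ratio 4.58, range 4.41 to 4.72). Enpp6 was at 5959.6 against 76.4 CPM. Myelinating oligodendrocytes had all 12 myelin markers higher (median log2 ratio 5.81, range 5.43 to 6.05). The myelin glycoprotein Mog was at 1572 against 7.22 CPM. Of 272 cells with a named type, 24 also carried the markers of another class at 25% or more of that class's median. Scaling by TMM and by median of ratios added 0.47 and 0.67 to the log2 ratios of microglia, 0.27 and 0.43 to those of newly formed oligodendrocytes, 0.01 and 0.15 to those of OPCs, 0.34 and 0.55 to those of endothelial cells, and 1.68 and 2.31 to those of myelinating oligodendrocytes, with every own-type median staying above 0.

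**Figure D2:**
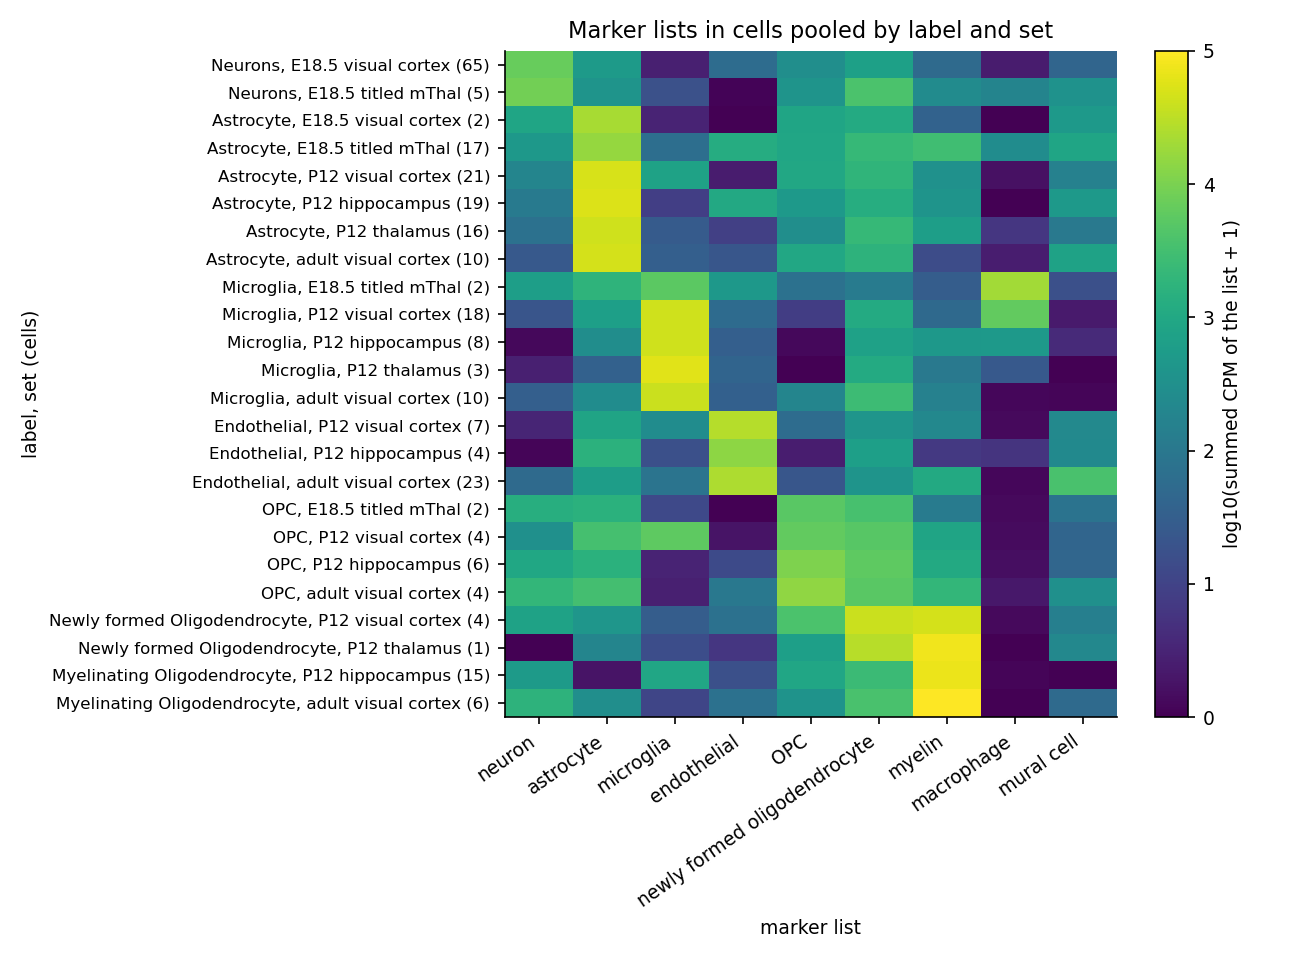
Heat map of log10 of the summed CPM plus 1 of 9 marker lists (columns) in each cell type label and set (lines), from reads pooled over the cells of each group. The highest values of the neuron, astrocyte, microglia, endothelial and oligodendrocyte lists lie in the groups of the matching label, and the myelin list is high in newly formed oligodendrocytes too.

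Neurons of E18.5 titled mThal and of E18.5 visual cortex differed in their regional transcription factors (5 against 65 cells). Tbr1, a factor of deep cortical layers, was without a read in the mThal neurons (0 against 91.8 CPM, counting intervals 0 to 0.419 and 89.7 to 93.8 CPM, at least 269-fold lower). In the other direction stood factors of the thalamus and diencephalon, 6 of 7 measured members higher (median log2 ratio 7.08, range 5.35 to 7.40, 8.20 at the floor, 5.35 without mThal cell 3 and 6.21 without mThal cell 27 and 6.14 without mThal cell 45). Tcf7l2, the Wnt pathway factor of thalamic neurons, was at 2836 against 19.9 CPM (log2 ratio 7.08, range 6.14 to 7.60, read in 3 of 5 against 9 of 52 cells), and Lhx9 at 366 against 0 CPM, carried by few cells (2 of 5 against 0 of 52 cells, log2 range 6.85 to 9.04). The zinc finger factors Zic1 (416 against 0 CPM, at least 11861-fold higher, read in 4 of 5 against 0 of 52 cells) and Zic4 (287 against 0 CPM, 3 of 5 against 0 of 52 cells) were higher too. Prox1 of the same list went the other way in pooled level (0.114 against 92.0 CPM, 809.7-fold lower with a counting interval of 145 to 31987), with a read in 1 of 5 against 7 of 52 cells. The telencephalon list as a whole had 4 of 7 members lower (median log2 ratio -1.74, range -5.25 to -1.44, -3.84 without mThal cell 27 and -5.25 without mThal cell 45). This median was near that of all measured genes (-1.49) and at percentile 7.71 of random lists, and Bcl11b (159 against 118 CPM, read in 2 of 5 against 26 of 52 cells) lay within 2-fold. The log2 ratio of 0.56 of Lhx2 rested on 1 mThal neuron (1 of 5 against 34 of 52 cells, log2 range -5.25 to 1.07).

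Other gene groups were compared in the same neurons. Cortical excitatory neuron markers were lower in the mThal neurons for 7 of 10 (median log2 ratio -3.08, range -4.68 to -2.61, -4.68 without mThal cell 27, percentile 0.560), including Tiam2 (0 against 213 CPM) and Cux2 (24.3 against 214 CPM), while Neurod1 was higher (959 against 105 CPM). Enc1, an actin-binding protein of developing neurons, had no read (0 against 8056 CPM, at least 23648-fold lower). Interneuron markers were lower for 7 of 8 (median log2 ratio -5.68, range -5.72 to -5.42, -6.90 at the floor, percentile 0.880). The GABA-synthesising enzyme Gad2 was at a log2 ratio of -6.93 (read in 0 of 5 against 19 of 52 cells) and Dlx1 at 0 against 70.5 CPM (0 of 5 against 18 of 52 cells). Only 16 of 71 E18.5 visual cortex cells carried 3 or more interneuron genes, so 5 neurons may hold none by chance and the list need not reflect region. Axon growth genes had 7 of 13 lower (median log2 ratio -1.21, range -1.27 to -0.70), no lower than the median of all measured genes though at percentile 0.270 of random lists. The lower members included the guidance receptors Nrp1 (3.29 against 630.1 CPM) and Robo1 (0.114 against 109.8 CPM), with Gap43 of growth cones higher (1148 against 239.7 CPM). With these cell numbers 64.3% of simulated unchanged genes lay beyond 2-fold. Cajal-Retzius markers were higher for 4 of 4 (median log2 ratio 6.94, range 1.88 to 7.35, 1.88 without mThal cell 3). Reln was at 1254 against 12.4 CPM, and the homeobox factor Meis1 was at 2374 against 17.5 CPM. In 100 draws of 5 visual cortex neurons, made for the telencephalon list alone, its median lay between -4.61 and 0.02. TMM and median-of-ratios scaling added 0.23 and 0.46, which turned no list named here.

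**Figure D3:**
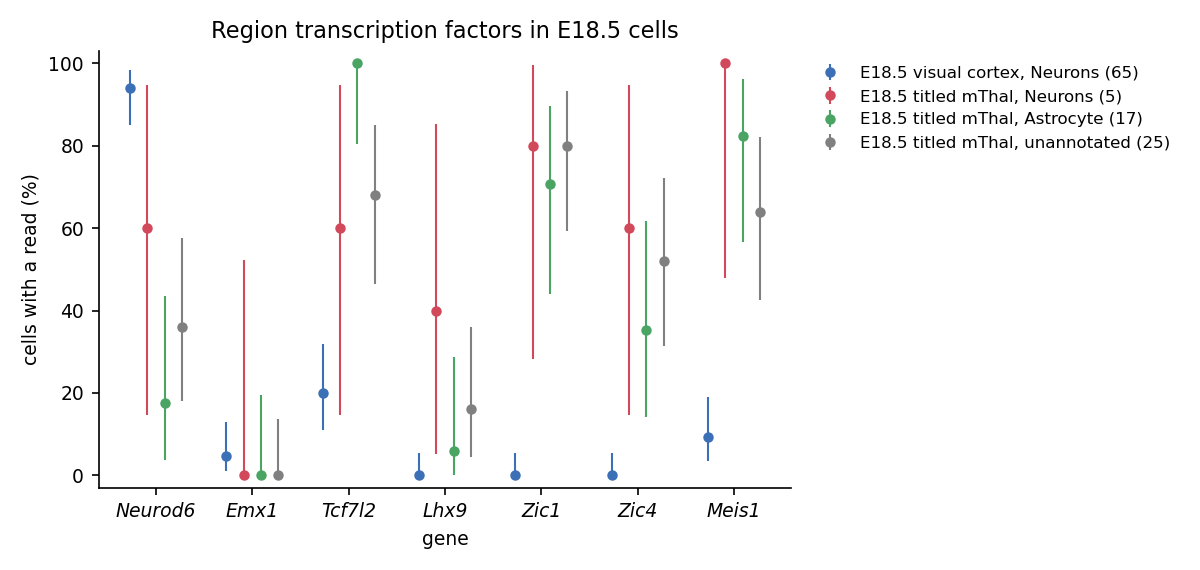
Share of cells with at least 1 read (y axis, percent, with Clopper-Pearson intervals as bars) of 7 regional genes (x axis) in E18.5 visual cortex neurons and in neurons, astrocytes and unannotated cells of the set titled mThal. All cells are counted here, without thinning. Zic1 was read in 0 of 65 visual cortex neurons and in 4 of the 5 neurons titled mThal.

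Astrocytes of P12 hippocampus and visual cortex had close levels of astrocyte markers, and a few regional factors differed in pooled level through few cells (19 against 21 cells). Astrocyte markers lay within 2-fold for 11 of 12 (median log2 ratio 0.16, range 0.02 to 0.24), the exception being the calcium-binding protein S100b (136 against 49.2 CPM, counting intervals 131 to 140.4 and 46.4 to 52.1 CPM, log2 ratio 1.44, range 0.53 to 1.91, read in 9 of 19 against 7 of 16 cells). The telencephalon factors had 2 of 6 lower in hippocampus (median log2 ratio -0.54, range -0.77 to -0.02). The cortical factor Emx1 was at 6.25 against 82.4 CPM, with a read in 3 of 19 against 4 of 16 cells, log2 range -4.89 to -1.92. Zic1 (10.7 against 0 CPM, at least 83.5-fold higher) and Zic4 (50.2 against 0 CPM, at least 392-fold higher) were read in some hippocampal astrocytes and in none of visual cortex. Zic1 had a read in 5 of 19 against 0 of 16 cells, log2 range 2.90 to 3.66, and Zic4 in 2 of 19 against 0 of 16 cells, log2 range 3.40 to 5.80. Maturation genes had a median log2 ratio of -0.51 (range -0.66 to -0.15), at percentile 0.860 of random lists, with Mfge8, a bridging protein of phagocytosis, at 1891 against 4080.0 CPM, Itih3 at 39.8 against 157 CPM and the synapse-maturation factor Chrdl1 at 24.9 against 112 CPM (read in 4 of 19 against 7 of 16 cells). Agt of the same list was higher (597 against 258 CPM, log2 ratio 1.21, range 0.75 to 1.78). Groups simulated without any change passed no smaller a share of genes through the naming rule (78 of 7430 against 89 of 9069 observed), so the genes here are members of fixed lists. Scaling by TMM and by median of ratios added 0.19 and 0.20, with no list named here turning.

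Astrocytes of P12 thalamus had no read of several telencephalon factors that were read in those of visual cortex (16 against 21 cells). Emx1 (0 against 82.4 CPM, counting intervals 0 to 0.198 and 78.7 to 86.1 CPM, at least 511-fold lower) and Fezf2 (0 against 38.5 CPM) had no read in thalamic astrocytes and were read in few of visual cortex (0 of 16 against 4 of 16 cells and 0 of 16 against 3 of 16 cells), and 5 of 6 telencephalon factors were lower (median log2 ratio -5.68, range -5.79 to -4.53, -7.32 at the floor, -4.53 without visual cortex cell 12), with Id2 within 2-fold (3133 against 2158 CPM). Fam107a, an actin-associated protein, had no read either (0 against 552 CPM, at least 3425-fold lower). Genes listed for astrocytes outside the telencephalon (named nonforebrain-type in the list, although the thalamus is forebrain) were higher for 5 of 8 (median log2 ratio 1.18, range 0.93 to 1.67), among them Agt (2109.6 against 258 CPM, log2 ratio 3.02, range 2.81 to 3.60) and the GABA transporter Slc6a11 (1564 against 333 CPM, log2 ratio 2.23, range 1.97 to 2.41). The others were the matrix protein Sparc (2462 against 1055 CPM), the glycine transporter Slc6a9 (31.1 against 5.80 CPM, read in 7 of 16 against 2 of 16 cells) and the filament protein Gfap (1637 against 742 CPM), which had a read in 4 of 16 against 11 of 16 cells, log2 range -0.88 to 1.48. Of the factors named for thalamus and diencephalon, the nuclear receptor Rora was higher (283 against 131 CPM), Tcf7l2 was within 2-fold (781 against 403 CPM, log2 ratio 0.95, range 0.55 to 1.11) and Prox1 was lower in pooled level (0.698 against 174 CPM, read in 3 of 16 against 3 of 16 cells), so the list had no single direction (1 of 5 higher and 3 lower, median log2 ratio -4.11, range -4.25 to 0.00, -6.65 at the floor, -0.40 without visual cortex cell 12 and 0.00 without visual cortex cell 58).

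Within the astrocyte programme itself the thalamic cells had more of the water channel Aqp4 (8079 against 2019.9 CPM, log2 range 1.70 to 2.22), the serine transporter Slc7a10 (663 against 220.1 CPM), Aldh1l1 (802 against 305 CPM) and S100b (326 against 49.2 CPM). The glutamate transporters Slc1a2 (5226 against 11844 CPM, log2 ratio -1.18, range -1.37 to -1.06) and Slc1a3 (6449.8 against 14844 CPM) and the glycolytic enzyme Aldoc (4286 against 8923 CPM) were lower, and Chrdl1 had no read (0 against 112 CPM). Wnt5a, a secreted Wnt ligand, was at 269 against 3.07 CPM and the lactate transporter Slc16a1 at 498 against 1.62 CPM. Immediate early and stress genes were lower for 11 of 14 (median log2 ratio -1.46, range -2.31 to -1.01, -2.31 without thalamus cell 17), including Egr1 (890.2 against 2392 CPM) and Nr4a1 (44.5 against 215 CPM). The microglial receptor P2ry12 was at 0.161 against 319.9 CPM, a gene of another cell type in the visual cortex arm. The median of the thalamus list rests on 5 members and was 0.95 with a minimum of 50 CPM and 1.03 with no minimum.

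Against hippocampal astrocytes, too, those of thalamus had telencephalon and immediate early genes lower (16 against 19 cells). The telencephalon factors were lower for 3 of 4 (median log2 ratio -5.48, range -5.59 to -5.03, -6.78 at the floor). Fam107a again had no read (0 against 348 CPM, at least 2157-fold lower). Meis1 (516 against 0 CPM, counting intervals 505 to 526 and 0 to 0.156 CPM, at least 4068-fold higher) and the immunoglobulin superfamily gene Igsf1 (2341 against 16.9 CPM, log2 ratio 7.03, range 6.87 to 11.01) were higher in thalamus. So were the ion channel Trpm3 (647 against 1.35 CPM) and the GABA-B receptor subunit Gabbr2 (208 against 3.25 CPM). Genes listed for astrocytes outside the telencephalon (median log2 ratio 1.05, range 0.88 to 1.29) and maturation genes (median log2 ratio 0.66, range 0.38 to 0.77) were higher for 4 of 8 and 6 of 15 members. Immediate early and stress genes were lower for 9 of 12 (median log2 ratio -1.95, range -2.57 to -1.71, -2.57 without thalamus cell 17). Atf3 was at 0.0537 against 81.8 CPM (read in 0 of 16 against 7 of 19 cells) and Btg2 at 748 against 3423 CPM. Tcf7l2 (781 against 306 CPM) and Rora (283 against 108 CPM) were higher and Prox1 (0.698 against 347 CPM, read in 3 of 16 against 8 of 19 cells) lower. Zic4 was at 1.56 against 50.2 CPM, a level that came from few cells, as it was read in 2 of 16 against 2 of 19 cells, log2 range -5.45 to -2.04. The thalamus list had no single direction (median log2 ratio -0.94, range -3.55 to -0.29, -3.55 without thalamus cell 6 and -0.29 without hippocampus cell 40), and its median stood at 0.08 with no minimum CPM.

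Astrocytes of P12 thalamus had more of the maturation, channel and uptake genes than those of E18.5 titled mThal (16 P12 against 17 E18.5 cells, the E18.5 region being the one in doubt). Maturation genes were higher at P12 for 8 of 14 (median log2 ratio 1.12, range 0.91 to 1.23) and astrocyte markers for 7 of 12 (median log2 ratio 1.77, range 1.53 to 1.96). Aqp4 was at 8079 against 1024 CPM, counting intervals 8039 to 8120.2 and 1012 to 1036 CPM, log2 ratio 2.98, range 2.68 to 4.43, and S100b at 326 against 17.6 CPM. Gfap was at 1637 against 6.01 CPM, log2 ratio 7.87, range 5.85 to 10.68, read in 4 of 16 against 1 of 17 cells. Ion and water channel genes were higher for 8 of 10 (median log2 ratio 2.34, range 2.11 to 2.61). The gap junction gene Gja1 was at 8914 against 1729 CPM, the potassium channel Kcnj10 at 699 against 216 CPM and the bicarbonate transporter Slc4a4 at 2511 against 502 CPM. Transmitter uptake genes followed for 7 of 12 (median log2 ratio 1.21, range 0.98 to 1.39), among them Slc7a10 (663 against 50.3 CPM). The cytokine Il33 was read at P12 and not at E18.5 (299 against 0 CPM, at least 2707-fold higher).

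Genes of progenitors and of neurons went the other way. The matrix protein Tnc (392 against 1663 CPM) and the filament Vim (307 against 766 CPM, log2 range -2.19 to -0.70) were lower at P12 in a progenitor list with 4 of 8 lower (median log2 ratio -1.04, range -1.38 to -0.70). Neuron markers were lower for 7 of 8 (median log2 ratio -4.87, range -5.03 to -3.94, -3.94 without mThal cell 48). Dcx was at 0.913 against 172 CPM, though with a read in 9 of 16 against 5 of 17 cells. Ribosomal protein genes were lower for 6 of 15 (median log2 ratio -0.94, range -1.26 to -0.67). The prostaglandin synthase Ptgds was at 4.03 against 6528 CPM with a log2 range of -11.62 to -5.56, and the haemoglobin genes Hbb-bs and Hba-a1 were read at E18.5 alone (0 against 112 CPM; 0 against 81.2 CPM). Among regional factors Tcf7l2 was within 2-fold (781 against 721 CPM), Rora was higher (283 against 113 CPM) and Prox1 lower (0.698 against 129 CPM, read in 3 of 16 against 7 of 17 cells). TMM and median-of-ratios scaling added 0.11 and 0.14, turning none of these lists.

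Microglia of P12 hippocampus and visual cortex had close levels of homeostatic genes (8 against 18 cells). Of 14 homeostatic microglia genes 13 lay within 2-fold (median log2 ratio 0.00, range -0.08 to 0.15), including P2ry12 (10915 against 10281 CPM, counting intervals 10855 to 10976 and 10241 to 10321 CPM, log2 ratio 0.09, range -0.11 to 0.22) and Cx3cr1 (7370.2 against 7212 CPM), with Selplg as the exception (1482 against 683 CPM), and the median over all measured genes was -0.35. Macrophage markers were lower in hippocampus for 8 of 8 (median log2 ratio -7.19, range -7.98 to -5.44, -8.15 at the floor, -7.98 without hippocampus cell 35 and -6.38 without visual cortex cell 54 and -5.44 without visual cortex cell 55). The mannose receptor Mrc1 was at 425 against 2643 CPM and the hyaluronan receptor Lyve1 at 0.0865 against 874 CPM (read in 1 of 8 against 3 of 18 cells). Lipid and lysosome genes were lower too for 5 of 9 (median log2 ratio -1.26, range -1.34 to -1.09). The lipid carrier Apoe was at 277 against 2120.4 CPM and the protease Ctsb at 3209 against 7665 CPM. Among the 18 visual cortex cells, 7 carried 1000 CPM or more of macrophage markers, as did 2 of the 8 hippocampal cells. Of the 8 macrophage genes, 5 or more were held by 4 of the 18 cells and 0 of the 8. A sample of 8 cells may hold none by chance, so the macrophage list need not reflect region. A comparison without such cells of 1000 CPM or more in either arm (6 against 11 cells) was added after seeing the data. There the lipid and lysosome median was -0.38, the log2 ratios of Apoe and Mrc1 were 0.53 and 2.51, and the homeostatic median was -0.27. Mrc1 is among the markers by which the cells were chosen, so its change follows from that choice. Cell cycle genes were higher for 10 of 14, yet their median of 3.03 was -1.19 without hippocampus cell 21, and simulated groups without any change passed no smaller a share of genes through the naming rule (158 of 5598 against 151 of 6896 observed).

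Adult astrocytes of visual cortex had less of the cholesterol synthesis, immediate early and ribosomal protein genes than those of P12 (10 against 21 cells). Genes at large were lower too, with a median log2 ratio of -2.36 over all measured genes and a median of 1666 against 3266 genes detected per cell, and the 3 lists were lower than that, at percentiles 0.0400, 0.210 and 0.280 of random lists. Cholesterol synthesis genes were lower for 13 of 15 (median log2 ratio -4.14, range -5.07 to -3.80, -5.07 without adult cell 29 and -5.07 without adult cell 31 and -5.07 without adult cell 39), among them Hmgcs1 (90.6 against 1612 CPM, counting intervals 83.1 to 98.6 and 1596 to 1629 CPM, log2 ratio -4.14, range -4.72 to -3.80), Cyp51 (0 against 485 CPM, at least 954-fold lower) and the squalene epoxidase Sqle (0.169 against 363 CPM). Immediate early and stress genes were lower for 12 of 14 (median log2 ratio -3.76, range -4.49 to -2.96, -3.92 at the floor, -4.49 without adult cell 30 and -2.96 without P12 cell 24). Fos was at 509 against 3742 CPM and Btg2 at 23.2 against 1639 CPM, while Dusp1 was at 748 against 324 CPM, with a log2 range of -0.60 to 1.45. Ribosomal protein genes were lower for 11 of 15 (median log2 ratio -3.34, range -6.17 to -2.88, -6.17 to -5.25 without any 1 of adult cells 26, 29, 31, 39 and 44). Rpl3 was at 0.169 against 412 CPM. Cell cycle genes were lower for 14 of 14, with a median of -6.06 that was -0.30 without P12 cell 4.

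The astrocyte programme itself differed less between the ages. Maturation genes had a median log2 ratio of -0.52 (range -0.65 to -0.36), at percentile 1.48 of random lists, with 5 of 15 lower and 2 higher. Agt had no read in adult cells (0 against 258 CPM, at least 508-fold lower), and the potassium channel Kcnj10 was at 111 against 657 CPM, log2 ratio -2.56, range -4.84 to -2.30. The glutamate transporter Slc1a2 (16032 against 11844 CPM) and Gja1 (6203 against 5893 CPM) were within 2-fold. The phagocytic receptor Mertk (2045 against 261 CPM) and the cystine transporter Slc7a11 (2215 against 582 CPM) were higher in adults, and the tetraspanin Cd9 was lower (0.169 against 936 CPM, 5528-fold lower with a counting interval of 992 to 218364). Xist, the noncoding RNA of the inactive X chromosome, had no read in adult astrocytes (0 against 680.3 CPM, at least 1339-fold lower). Of any label, 0 of 61 adult cells carried 10 Xist reads, which allows a share of up to 5.87% (Clopper-Pearson), or 4.92% as 3 counts of the total. In P12 visual cortex 26 of 60 cells carried 10 or more Xist reads and 27 of 60 as many Y-linked reads. Sex and age therefore move together in part in the adult comparisons. The adult arm was shallow, with 5903562 reads against 23444415 and only 3 of its 10 cells deep enough for shares of cells. The 2 other scalings, TMM and median of ratios, added 0.21 and 0.60, and the second of these brought the maturation median to 0.07.

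Adult microglia of visual cortex had few or no reads of macrophage and interferon genes, which at P12 lay mainly in the 7 cells with 1000 CPM or more of macrophage markers (10 against 18 cells, median over all measured genes -0.71). Homeostatic genes lay within 2-fold for 10 of 14 (median log2 ratio -0.43, range -0.54 to -0.18). P2ry12 was at 6086 against 10281 CPM, counting intervals 6043 to 6129 and 10241 to 10321 CPM, log2 ratio -0.76, range -0.84 to -0.62 and Cx3cr1 at 6863 against 7212 CPM. Olfml3 (768 against 3077 CPM, log2 range -2.34 to -1.71) was lower, and Tmem119 (1136 against 449.6 CPM) and the fructose transporter Slc2a5 (718 against 205 CPM) were higher. Macrophage markers were lower for 8 of 8 (median log2 ratio -8.41, range -8.52 to -7.90, -10.11 at the floor). Mrc1 was at 0.0797 against 2643 CPM, 33168-fold lower with a counting interval of 5953 to 1310085 and F13a1 at 0.0797 against 1409 CPM (read in 1 of 10 against 4 of 18 cells). Interferon response genes were lower for 8 of 8 (median log2 ratio -6.26, range -6.36 to -4.94, -6.73 at the floor, -5.32 without P12 cell 23 and -5.65 without P12 cell 34 and -4.94 without P12 cell 55). Oasl2 was at 0 against 92.5 CPM (read in 0 of 10 against 2 of 18 cells). Inflammatory cytokine genes were higher for 5 of 11 (median log2 ratio 0.59, range 0.35 to 1.30, 1.30 without P12 cell 44), among them interleukin-1 alpha, Il1a (6201 against 583 CPM, log2 ratio 3.41, range 3.15 to 3.93), and the activation marker Cd83 (6789 against 2269.6 CPM), while the chemokine Cxcl10 had no read in adults (0 against 669.9 CPM, at least 2802-fold lower, read in 0 of 10 against 4 of 18 cells). Apoe was at 1.35 against 2120.4 CPM, log2 ratio -9.82, range -10.82 to -8.77.

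Several of these values depend on the 7 P12 cells. Without them, fewer than 3 genes of the macrophage and of the interferon list reached 10 CPM in either arm, and the log2 ratios were 0.11 for F13a1, -4.57 for Mrc1, -5.14 for Apoe and -0.52 for Cxcl10. The cells were chosen by macrophage markers, so the changes of that list, of F13a1 and of Mrc1 follow from the choice. Of the 7, cells 1, 2 and 35 held only 1 or 2 of the macrophage genes, with P2ry12 at 11065 to 13338 CPM. Il1a (log2 ratio 2.57) and Cd83 (6789 against 2392 CPM) stayed beyond 2-fold. Of the homeostatic genes 5 of 14 were then lower and 1 higher (median log2 ratio -0.69), with P2ry12 at -1.17 and Tmem119, at 0.71, within 2-fold.

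The antigen presentation list rested on 1 adult cell. Its median of 1.53 came with H2-Aa at 1448 against 0 CPM, H2-Ab1 at 1011 against 0.0405 CPM and Cd74 at 1784 against 113 CPM, all read in the adult cell numbered 1, and without that cell the median was 0.08 and the homeostatic median -0.29. These comparisons without single cells or the 7 cells were added after seeing the data. The cell numbered 1 stands for 2 deposited libraries, cells 1 and 6, whose counts lay far closer than those of any other pair (chi-square per gene 4.08 against 79.2 or more in the next 4 pairs) and were counted as 1 sample. TMM and median-of-ratios scaling added 0.10 and 0.19, turning no list named here.

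**Figure D4:**
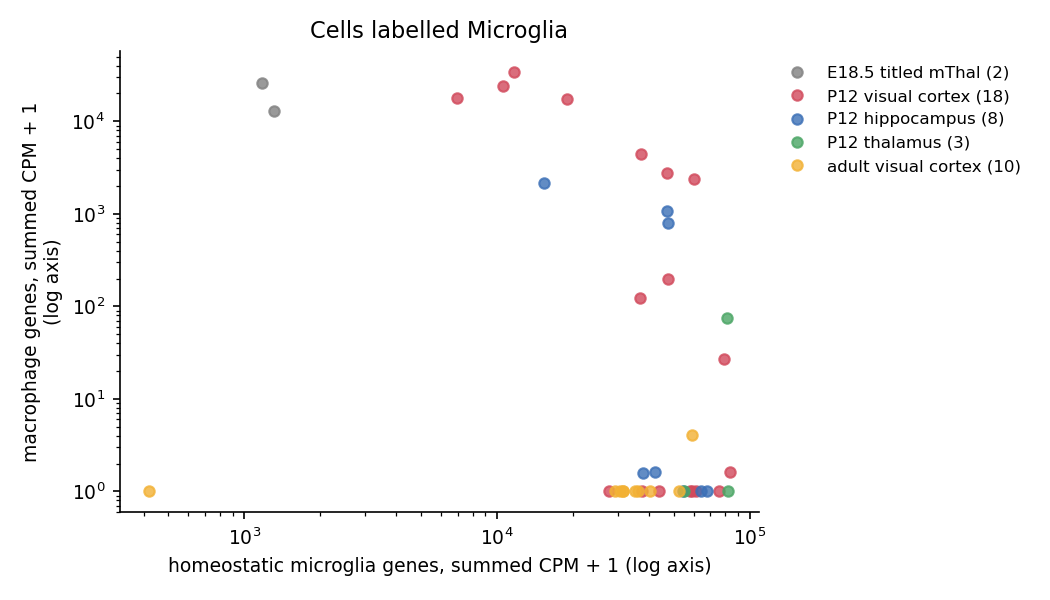
Each point is 1 cell labelled Microglia, coloured by set, with the summed CPM plus 1 of homeostatic microglia genes on the x axis and of macrophage markers on the y axis, both logarithmic. Of the P12 visual cortex cells, 4 lie at 17237 to 34359 CPM of macrophage markers, and 1 adult cell lies at 417 CPM of homeostatic genes.

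Adult endothelial cells of visual cortex had less of the basement membrane genes and more of the interferon and immediate early genes than P12 ones (23 against 7 cells, median over all measured genes 0.39). Basement membrane genes were lower for 10 of 12 (median log2 ratio -2.23, range -2.77 to -1.21, -1.21 without P12 cell 39). The nidogen Nid1 was at 0.0405 against 837 CPM, counting intervals 0.00102 to 0.226 and 818 to 856 CPM, 20679-fold lower with a counting interval of 3710.3 to 816872, the matrix protein Sparc at 1287 against 8539 CPM, log2 ratio -2.73, range -3.06 to -2.43 and the collagen Col4a1 at 243 against 807 CPM (log2 range -2.19 to -0.40). Vascular growth genes were lower for 7 of 8, with a median of -4.16, -5.01 without adult cell 49 and 0.03 without P12 cell 39. The direction of that list thus rests on 1 P12 cell. The VEGF receptor Kdr was at 412 against 1166 CPM (log2 range -1.93 to -1.16). Interferon response genes were higher for 11 of 12 (median log2 ratio 6.07, range 5.50 to 6.35, 7.29 at the floor), with Ifit1 (245 against 0 CPM, at least 743-fold higher) and Usp18 (251 against 0 CPM, at least 763-fold higher), which were read in 2 of 20 against 0 of 7 cells and in 6 of 20 against 0 of 7 cells. Antigen presentation genes were higher for 6 of 6 (median log2 ratio 2.61, range 1.97 to 4.27, 1.97 to 1.98 without any 1 of adult cells 27 and 40 and 3.62 to 4.27 without any 1 of P12 cells 9 and 26). H2-K1 was at a log2 ratio of 3.22. Immediate early and stress genes were higher for 13 of 16 (median log2 ratio 2.08, range 1.72 to 2.37). Egr1 was at 7250.4 against 973 CPM, log2 ratio 2.90, range 2.68 to 3.50, Atf3 at 1844 against 27.4 CPM and the heat shock gene Hspa1a at 314 against 0.110 CPM.

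Barrier transport genes were within 2-fold for 8 of 13 and lower in adults for 5 (median log2 ratio -0.79, range -0.97 to -0.48). The lower ones included the monocarboxylate transporter Slc16a1 (722 against 3411 CPM, log2 ratio -2.24, range -2.84 to -1.95), the thyroid hormone transporter Slco1c1 (2166 against 6094 CPM, log2 ratio -1.49, range -1.70 to -1.09) and the lipid transporter Mfsd2a (log2 ratio -1.85). The efflux pump Abcb1a (751 against 391 CPM), the organic anion transporter Slco1a4 (5379 against 3229 CPM) and the glucose transporter Slc2a1 (1504 against 1440.0 CPM) were within 2-fold. Itih5, a hyaluronan-associated protein, had no read at P12 (1881 against 0 CPM, at least 5711-fold higher). Mural cell markers were higher for 7 of 7 adult values, with Rgs5 at 3009 against 173 CPM (read in 8 of 20 against 3 of 7 cells) and a median of 4.28 (5.81 at the floor, 0.27 without adult cell 52 and 4.92 without P12 cell 9). Without the 5 adult cells that carried 1000 CPM or more of mural markers, a comparison added after seeing the data, the barrier median was -0.74, the log2 ratio of Rgs5 -2.67 and the interferon median 6.24. Other scaling (TMM, then median of ratios) added 0.16 and 0.06, turning no list named here.

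**Figure D5:**
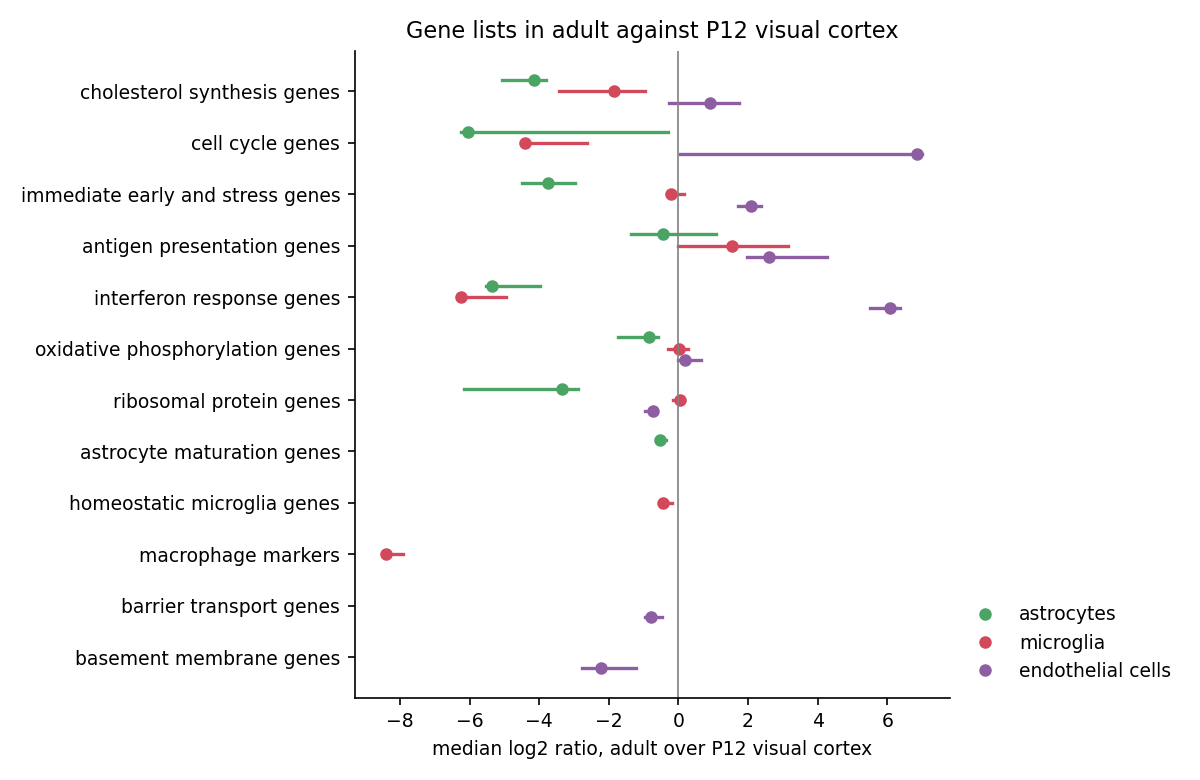
Median log2 ratio of adult over P12 visual cortex (x axis) of 12 gene lists (y axis) in astrocytes, microglia and endothelial cells, with bars for the range over left-out cells. Interferon response genes lie at 6.07 in endothelial cells and at -6.26 in microglia. Median-of-ratios scaling turns the sign of the maturation and antigen medians of astrocytes and, outside the figure, of their marker and channel medians and of the microglia marker median.

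Myelinating oligodendrocytes differed from OPCs by the myelin and precursor genes themselves (21 against 16 cells of all sets), genes on which the labels may rest. Every myelin marker was higher, 12 of 12 (median log2 ratio 8.19, range 7.79 to 9.18, 10.44 at the floor, 9.18 without adult visual cortex cell 62 and 9.08 without P12 hippocampus cell 44). Mal was at 4126 against 0.0487 CPM, counting intervals 4109.8 to 4141 and 0.00123 to 0.271 CPM, 84767-fold higher with a counting interval of 15214 to 3348118 and Mog at 1572 against 0 CPM, at least 10764-fold higher. The lysophosphatidic acid receptor Lpar1 was at 6950.3 against 0.0487 CPM. OPC markers were lower for 9 of 11 (median log2 ratio -8.71, range -8.84 to -8.43, -10.04 at the floor). Pdgfra was at 0 against 4899.5 CPM, at least 104367-fold lower and the proteoglycan Vcan at 0 against 1351 CPM, while Olig2, a factor of the whole lineage, was higher (397 against 84.4 CPM, log2 ratio 2.22, range 1.55 to 4.33) but lower with cells of adult visual cortex alone (log2 ratio -1.62). Of the genes of newly formed oligodendrocytes, Gpr17 was lower (1.25 against 1774 CPM) and Enpp6 higher (442 against 0.195 CPM, read in 8 of 21 against 1 of 15 cells). Oxidative phosphorylation genes were lower for 10 of 13 (median log2 ratio -2.90, range -3.12 to -2.29, -2.29 without P12 hippocampus cell 57), no lower than the median of all measured genes (-3.15) though at percentile 1.13 of random lists. Atp5a1 was at 94.1 against 769 CPM. TMM and median-of-ratios scaling added 1.65 and 1.89 here, enough to turn the ribosomal protein (-1.36), cholesterol synthesis (-0.08), immediate early (-0.40) and newly formed oligodendrocyte (-1.16) medians to values above 0. In P12 hippocampus the 15 myelinating cells and 1 astrocyte carry a block of lower cell numbers and the 6 OPCs the upper one, and without the lower block the myelin median was 9.83.

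Myelinating oligodendrocytes of adult visual cortex and of P12 hippocampus, which differ in age and in region, were compared last (6 against 15 cells). They differed in depth and block as well, with a median of 1335832 against 4120108 reads per cell and all 15 P12 cells in the lower block of cell numbers, so age, region and block cannot be told apart. Myelin markers were higher in the adult cells for 6 of 12 and within 2-fold for the other 6 (median log2 ratio 0.98, range 0.71 to 1.08). The myelin basic protein Mbp was at 14371 against 1858 CPM, counting intervals 14294 to 14449 and 1847 to 1869.7 CPM, log2 ratio 2.95, range 2.82 to 3.15, and Mag at 2597 against 751 CPM. Il33 (3417 against 0 CPM, at least 62349-fold higher) and the noncoding RNA Neat1 (1849 against 0 CPM, at least 33749.6-fold higher) had no read in P12 hippocampus. Immediate early and stress genes were higher for 10 of 13 (median log2 ratio 5.58, range 2.56 to 5.87, 5.85 at the floor, 3.87 without adult cell 2 and 2.56 without adult cell 15 and 4.63 without adult cell 41). Fos was at 5072 against 619 CPM, Jun at 273 against 0.585 CPM and Dusp1 at 625 against 1.92 CPM. Oxidative phosphorylation genes (median log2 ratio 3.83, range 1.54 to 4.40, 1.54 without adult cell 14) and ribosomal protein genes (median log2 ratio 2.14, range 1.81 to 3.49, 3.49 without hippocampus cell 2) were higher for 9 of 13 and 11 of 15, at percentiles 88.8 and 93.9 of random lists. The ribosomal median was close to that of all measured genes (2.07, with a median of 2288 against 1182 genes detected per cell), and the myelin median lay below it. Cholesterol synthesis genes were lower for 7 of 11 (median log2 ratio -1.35, range -2.35 to -1.13, -2.35 without adult cell 4). Hmgcs1 was at 509.5 against 1304 CPM. TMM and median-of-ratios scaling shifted this comparison by -1.31 and -1.48 and turned the myelin median to -0.32 and -0.50. The direction of the myelin list thus depends on the scaling.

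Several of the named genes have these positions in GRCm38, the assembly also called mm10, and each is a protein-coding gene of the GENCODE annotation. Tcf7l2 lies on chromosome 19 from 55741820 to 55933654 and Zic1 on chromosome 9 from 91358058 to 91365810. Fam107a lies on chromosome 14 from 8296274 to 8318023, Mrc1 on chromosome 2 from 14229392 to 14332057, Itih5 on chromosome 2 from 10153571 to 10256529, Pdgfra on chromosome 5 from 75152292 to 75198215 and Il33 on chromosome 19 from 29925114 to 29960718.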

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

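Of the tests in this part, the one on interneuron and excitatory genes was planned before its result was seen and the other tests were chosen after the result was seen.

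Macrophage markers in the P12 visual cortex cells labelled Microglia came as a block, with 4 of 18 cells holding 5 or more of the 8 genes, 90.4% of the pooled signal and 17237 to 34359 CPM each. Reads leaking evenly from other libraries are argued against by the other named cells of the set, whose pooled level was 0.00864% of that in cells labelled Microglia. A candidate explanation is that whole macrophages were counted under the label Microglia, since the 4 cells had at most 1462 CPM of P2ry12 against at least 3758 CPM in the others, and the most abundant markers over all 18 cells were Mrc1 (2643 CPM), F13a1 (1409 CPM) and Lyve1 (874 CPM), though the FACS gate, which the sources used here do not describe, would decide whether such cells were collected. A macrophage and a microglial cell in 1 library are argued against in cells 30, 54 and 55 by single genes. There P2ry12 was at most 2.06% of its lowest level in the other 14 cells and Olfml3 at most 47.9 CPM against at least 221 CPM. The homeostatic sums of these cells, 6959.7 to 11625 CPM against a median of 45461 CPM over all 18, do not by themselves exclude a mixture. In cell 23, with P2ry12 at 38.9% of that level and no read of Olfml3, the mixture stays open, as does, untested, a difference between the ages or regions for all 4, whose homeostatic genes summed to at least 6959.7 CPM.

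Xist and Y-linked genes were each read 10 times or more in 17 of 71 E18.5 visual cortex cells (23.9%, Clopper-Pearson interval 14.6 to 35.5%), against 2 of 51 in E18.5 titled mThal, 1 of 60 in P12 visual cortex and 0 of 68 in P12 hippocampus. Even leakage between libraries is argued against by 56.3% of the cells having no read of the weaker signal. Libraries of 2 cells may account for it, since 10 of the 11 such cells deep enough to be thinned (90.9%) lay above the set's median of 3145 genes detected at equal depth. The planned test left this open, because 15 of 16 cells with interneuron genes also had excitatory genes (93.8%) but so did 70 of all 71. The design offers no biological explanation, so none was tested, and without these cells the telencephalon and thalamus medians of E18.5 neurons were -1.76 and 7.27. Libraries of 2 cells of the same sex would not carry both signals. The share of 23.9% is therefore no estimate of all libraries of 2 cells, and some may remain in these medians.

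The neuron numbered 43 of E18.5 titled mThal stood apart from the other 4, with 2197 genes detected against 3200 in the nearest, the only such cell in 39 groups tested, and since chance flags about 1 in 20 groups this is no more than chance gives.

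Between cell types, 7 lists were compared for adult over P12 visual cortex, and in 3 of them the medians of 2 types lay on opposite sides of 0 whichever cell was left out, differences that were not tested. Interferon response genes were higher in adult endothelial cells (6.07) and lower in adult astrocytes (-5.37, on 3 measured genes) and microglia (-6.26), differences of 11.44 and 12.33. In microglia this rests mainly on the P12 cells with macrophage markers. P12 cell 34, among the cells that alone moved that median, had 0 CPM of those markers. Immediate early and stress genes were at 2.08 in endothelial cells and -3.76 in astrocytes, a difference of 5.84. Cell cycle genes were at 6.85 in endothelial cells, on 3 measured genes and 0.06 without adult cell 52, against -6.06 in astrocytes (-0.30 without P12 cell 4) and -4.42 in microglia, differences of 12.90 and 11.27.

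Cells that entered no comparison carried markers of known classes. The median per cell of the summed neuron markers was 3445 CPM in 4 unannotated cells of E18.5 visual cortex, 1619 CPM in 25 of E18.5 titled mThal, 4443 CPM in 5 of P12 visual cortex, 4043 CPM in 16 of P12 hippocampus and 5101 CPM in 2 of adult visual cortex. Mural cell markers summed to 99094 CPM in the purple cell of P12 visual cortex, fibroblast markers to 55292 CPM in the unannotated cell of P12 thalamus, and choroid plexus markers to a median of 195639 CPM in 6 purple cells of adult visual cortex.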

How the results depend on the processing

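The alternatives that leave out cells by their macrophage, mural, homeostatic or sex-linked reads, count the near-identical libraries as 2 cells or thin to a lower depth were chosen after seeing the data, and the rest were planned. Of 194 values of the leading list medians, the neuron share and the number of genes named, 161 stayed within 1.5 times of the value in the report, 26 moved by more, and 7 changed sign or went to 0. Of 1392 values of single genes the numbers were 1159, 223 and 10. The number of genes named, 255, is the cap itself of 5 genes per cell type and 10 per direction of a comparison, since more genes than that met the naming rule. Of these genes, the conditions on the share of cells were still met by 175 with 5 reads in the unthinned cell and 194 with all cells thinned to the lower depth. Leaving out cells under 1000 genes removed no cell, as the lowest had 1011, so it says nothing. Adult endothelial cells and microglia of hippocampus against visual cortex held no cell with markers of another class and have no value under that alternative. No paired analysis was possible because the numbers in the titles only name cells and no comparison has a test. Depth limits the adult astrocytes most, of which 3 of 10 reached the thinning depth.

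With other scaling, the myelin median of myelinating oligodendrocytes over other cells was 7.34 (TMM) and 7.91 (median of ratios), that over OPCs 9.02 and 9.14, and that of adult visual cortex over P12 hippocampus turned to -0.32 and -0.50. Median-of-ratios scaling put the microglia markers at 8.37 and the maturation genes of adult astrocytes at 0.0714. These factors scale the counts of every gene of a comparison alike, but with 1 CPM added the log2 ratios of genes near 0 move by less. Why the factors differ from the totals was not tested.

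With 5 CPM added, medians over genes near 0 in 1 arm shrank by construction, to 3.94 for neuron, 6.80 for microglia and 6.72 for endothelial markers, 6.71 for myelin over OPCs and -2.08 for the thalamus factors of thalamic over visual cortex astrocytes. With 0.1 CPM added the last 2 were 11.51 and -7.35. The thalamus list of astrocytes has 5 measured members that go both ways, so its median depends on which are counted. It turned to 1.03 with no minimum and 0.95 with a minimum of 50 CPM against visual cortex, and to 0.0755 with no minimum against hippocampus. Against visual cortex it was -1.72 without cells carrying markers of another class, a setting that put microglia markers at 9.37. The cause was not tested for either.

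Leaving out 1 cell at a time gave -4.25 to 0.00 for this list against visual cortex, -3.55 to -0.29 against hippocampus, -5.25 to -1.44 for the telencephalon factors of E18.5 neurons, 7.73 to 8.46 for microglia markers, 3.20 to 4.06 for OPC markers and 7.79 to 9.18 for myelin over OPCs. Draws of 5 visual cortex neurons put the telencephalon median between -4.61 and 0.0187, so its direction depends on the few cells drawn. Myelin over OPCs was 9.83 without the lower block of cell numbers in P12 hippocampus and 10.02 in adult visual cortex alone, where Olig2 turned to -1.62, and the cause was not tested. The share of neurons in E18.5 visual cortex was 57.4% with both E18.5 sets pooled and 97.0% of named cells, as other cells are then counted.

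Single genes turned where the cells that carried their reads were left out. Without cells with 1000 CPM of macrophage markers, adult over P12 microglia had F13a1 at 0.11 and Oasl2 at 0.00, and hippocampal over visual cortex microglia had Apoe at 0.53, Lyve1 at 0.16 and Mrc1 at 2.51. Without the adult cell under 1000 CPM of homeostatic genes, H2-Aa was at 0.00 and H2-Ab1 at -0.0573, and without cells with 1000 CPM of mural cell markers adult endothelial cells had Rgs5 at -2.67.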

Other observations

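All tests in this part, that of B cell genes and that of microglia genes in the same cell, were chosen after the result was seen.

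The cells without a named type held gene groups that the comparisons leave out. The 6 purple cells of adult visual cortex had Ttr, the thyroid hormone carrier made by the choroid plexus, at a median of 189301 CPM (51.8 to 427446), with Prlr at 1268, Clic6 at 1062 and Folr1 at 831 CPM. The purple cell of P12 visual cortex instead had Rgs5, a regulator of G protein signalling in pericytes, at 81133 CPM, Vtn at 8029 CPM and Pdgfrb at 2179 CPM, so 1 label covered cells with unlike genes. The unannotated cell of P12 thalamus had the collagens Col1a2 at 13608 CPM and Col3a1 at 10815 CPM and the proteoglycan Dcn at 11097 CPM.

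Among unannotated cells with neuron markers, those of P12 hippocampus (16 cells) had Dcx, a microtubule protein of young neurons, at a median of 1193 CPM, the factor Neurod1 at 894 CPM and Calb2 at 95.3 CPM. Those of P12 visual cortex (5 cells) had the interneuron genes Dlx6os1 at 536 CPM and Dlx1 at 126 CPM. The 2 of adult visual cortex had Reln, an extracellular protein of Cajal-Retzius cells, at 467 and 4160.3 CPM and Trp73 at 2.07 and 996 CPM. In E18.5 titled mThal the 25 unannotated cells had Reln at a median of 148 CPM, with a read in 14 of them, and Zic1 was read in 20 of them. Over all cells of that set, without thinning, Zic1 was read in 37 of 51, against 0 of 71 in E18.5 visual cortex.

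The 2 cells of E18.5 titled mThal labelled Microglia had macrophage marker sums of 12873 and 25806 CPM and homeostatic sums of 1307 and 1174 CPM, against a median homeostatic sum of 45461 CPM in P12 visual cortex. Cells labelled Astrocyte in P12 visual cortex had P2ry12 at 319.9 CPM and C1qb at 95.9 CPM, against 1.14 and 0.296 CPM in hippocampus. Xist was read 10 times or more in 41 of 71 cells of E18.5 visual cortex, 21 of 51 of E18.5 titled mThal, 26 of 60 of P12 visual cortex, 17 of 68 of P12 hippocampus, 9 of 21 of P12 thalamus and 0 of 61 of adult visual cortex, where Y-linked genes were read in 41.

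The adult cell numbered 1 labelled Microglia may be a B cell under that label, a hypothesis that its test left open. Its homeostatic microglia genes summed to 417 CPM, 1.19% of the median of the other 9, which argues against a microglial cell and a B cell in 1 library. Its most abundant genes were Cd74 (18164 CPM), H2-Aa (15698 CPM) and Ets1 (15183 CPM), and of 10 listed B cell genes 5 had 10 reads or more, Ly6d (4080.4 CPM), Cd22 (3821 CPM), Cd79a (1508 CPM), Ms4a1 (740.2 CPM) and Cd79b (631 CPM), against 0 of the 10 in any other adult cell labelled Microglia. These 5 had all been seen before they were listed. The rule, first set at 5 genes of the 10, was tightened after its result was seen to need 2 genes not looked at before, and the 4 of that kind (Pax5, Ebf1, Blk and Fcrla) had no read. The FACS gate, not described in the sources used here, would decide whether such a cell could be collected.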
